A study of Rattus norvegicus with 15 samples.

How the data were processed

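Poly(A)-selected RNA was sequenced from cultured rat tracheal epithelial cells in 15 libraries, which the labels divide into control, CSE and CSE with naringenin, 5 libraries each. Per the labels' protocols, cells freed from rat trachea by pancreatin were expanded in PneumaCult-Ex Plus medium and then kept for weeks at an air-liquid interface, where airway basal cells differentiate into ciliated and secretory cells. Strand-specific libraries were made with unique molecular identifiers in the adapters and read as pairs of 150 bases on an Illumina NovaSeq, per the labels' protocols. Treatments were 10% CSE for 24 h, with or without 100 µM naringenin from 4 h before. The labels give CSE as an abbreviation that is not expanded here. They name no strain, animal or culture for any library, so p-values measure only the spread between these samples, which may be technical.

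The values used are the counts per gene and library as the authors deposited them, whole numbers that were not normalized. FPKM values, fragments per kilobase of gene and 1e6 fragments, stand beside the counts in the deposited table and were computed by the authors. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR, with no role or order. Whether reads with the same molecular identifier were merged before counting, and whether counting used the strand, is not given in the sources used here, and neither is the genome build. Gene identifiers, symbols and coordinates are those of the deposited table, and coordinates count from 1 as printed there. All sample columns of the table matched 1 sample each by name. Counts of genes with near-identical copies, such as the Akr, Gst, Adh, Ugt1a, Scd and Hspa families, are uncertain where the counting could split reads between copies.

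The table holds 21969 genes, of which 15860 passed edgeR's filterByExpr over the 3 groups and were tested. Library totals ran from 55.1 to 60.6 M counts (1 M is 1e6), so that 3 counts, taken as the floor of detection, equal 0.0495 to 0.0545 CPM in a library. Such floors cover counting error only. Per-library levels are CPM (counts per 1e6, scaled by TMM), computed here from the deposited counts, and are given as mean ± SD over 5 libraries. Replicates were compared pairwise by a chi-square per gene. The median over genes was 2.94 to 6.21 for the 6 pairs of replicates within a library set (defined below) and 8.36 to 24.3 for the 24 other pairs, against 0.455 from sampling alone, so no pair was taken as a repeated deposit of 1 library. This comparison does not exclude repeat libraries of 1 culture, and n counts libraries.

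Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, 1 fit of all 15 libraries with group as the only term) and Benjamini-Hochberg adjustment over genes, and a gene counts as past the threshold at an adjusted p under 0.05. Standard errors are those of the log2 fold change, and fold changes carry the sign of the first group minus the second. Unless another tool is named, an adjusted p given for a gene is edgeR's. On simulated counts with 200 changed genes, the CSE versus control fit of 15645 genes recovered 29.9%, 58.2% and 83.3% of the changes of 1.5-fold, 2-fold and 4-fold with 0 false calls. For CSE with naringenin versus CSE (15634 genes) the shares were 23.9%, 64.2% and 83.3% with 0 false calls, and for CSE with naringenin versus control (15640 genes) 29.9%, 53.7% and 81.8% with 2 false calls. The simulated spread was estimated with the library set (defined below) and without group, so real group differences counted as spread. In CSE versus control 3363 genes were called, far more than the 200 simulated changes. These shares may therefore not describe the real fits.

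The test, the samples in the fit, the rule for named genes and 25 gene lists were fixed before the data were examined. Of 447 list members, 416 matched a gene of the table, 2 of them through a synonym (Muc5ac as AABR07006032, Car9 as Ca9). Foxj1 did not match and was not analysed here. The lists cover antioxidant genes controlled by NRF2, AhR targets, other xenobiotic and aldehyde enzymes, inflammatory mediators, interferon-induced genes, unfolded protein and integrated stress response genes, heat shock proteins, p53 targets, proliferation, cilia, mucins and goblet cells, club cells, basal cells, squamous cells, ion and fluid transport, junctions, matrix remodelling, cholesterol synthesis, fatty acid metabolism, and hypoxia and glycolysis. The remaining lists are markers of stroma, leukocytes, endothelium, and rare neuroendocrine, tuft and cartilage cells, plus mitochondrially encoded genes as a sign of RNA quality. Each list was tested against all other genes with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons. A list score is the mean over its tested members of log2 CPM (prior count 2) minus the gene's mean over all libraries.

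Genes named in the text are, per comparison, the 6 largest rises and 6 largest falls among genes past the threshold with a symbol, a mean of at least 1 CPM and no overlap between the groups. To these come up to 4 members with the smallest adjusted p of each list that passed its test or had at least 3 members past the threshold, the fixed genes Cyp1a1, Cyp1b1, Hmox1, Nqo1, Muc5ac, Foxj1, Scgb1a1, Krt5, Il6, Il1b and Cftr, and 6 genes that changed in opposite directions in 2 comparisons. Placeholder names (LOC, RGD, AABR07 and NEWGENE) did not count as symbols; NEWGENE was added to these after its value was seen. Other genes are named only with the remark that they were chosen after their values were seen. Results of 4 genes are not reported here. These genes stay in all tests and counts but were left out, after the results were seen, of the search for single libraries that stand apart.

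Hierarchical clustering of the libraries showed 3 sets that cut across the groups. Set 1 holds control 1 and 2, CSE 1 and 3, and CSE with naringenin 3 and 4. Set 2 holds control 3 and 4, CSE 2 and 4, and CSE with naringenin 1 and 2, and set 3 holds replicate 5 of each group. The sets were found in the data, no label names them, and a fit with the set as a block was added after seeing the data. The spread in that fit rests in part on pairs of libraries of 1 set and group, which may be repeats of 1 culture. Its p-values may therefore be too small, and fewer genes passed on counts summed per set and group. Alternatives planned beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter of 5 CPM in 5 libraries, fits of only the 2 groups compared, the replicate number as a block, a 2-fold minimum, each library left out, CSE libraries split between comparisons, camera with an estimated correlation, and fry. Added after seeing the data were the set block, libraries of 1 set and group summed, set 3 left out, limma on log2(FPKM + 1), and list tests without control library 5. Tests over KEGG pathways, whose names are in the deposited table, were also added then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.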

Results

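RNA was sequenced from cultured rat tracheal epithelial cells that had differentiated at an air-liquid interface, a culture with medium below and air above the cells. The 15 libraries comprise 5 controls, 5 from cells given 10% CSE for 24 h and 5 from cells given the same CSE with 100 µM naringenin, a citrus flavanone added 4 h beforehand. Library totals averaged 58.3 ± 1.01, 58.9 ± 1.27 and 57.5 ± 1.95 M counts (SD, n = 5) in these groups. Mitochondrial genes took 8.51% ± 0.302, 8.35% ± 0.777 and 8.51% ± 0.672 of the counts. A median of 24.8% of a gene's variance lay between the groups, 32.4% between the 3 library sets that cut across the groups, and 30% within both. Sets 1 and 2 hold 2 libraries of each group and set 3 holds 1. With group in the model, 8071 of the 15860 genes tested differed between sets (edgeR). The sets were found by clustering these same counts, so the 32.4% and this count were in part fixed in advance. No library received naringenin alone, so its own effect on these cells was not measured.

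The first comparison asks which transcripts change in airway epithelium exposed to CSE. Cyp1a1, a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons and is switched on by the aryl hydrocarbon receptor (AhR), rose 64-fold, from 3.36 ± 0.967 CPM (SD, n = 5) in control to 215 ± 80.9 CPM in CSE libraries. Cyp1b1, a related AhR-controlled cytochrome, rose 29.4-fold, from 9.01 ± 2.76 to 265 ± 70.1 CPM. Nqo1, a quinone reductase under control of the antioxidant factor NRF2, rose 3.48-fold to 3881 ± 134 CPM, and Hmox1, the stress-induced heme oxygenase, 5.74-fold to 989 ± 406 CPM. In the other direction, the monocyte chemokine Ccl2 fell from 7.19 ± 4.09 to 0.394 ± 0.319 CPM, and tenascin C (Tnc), a matrix glycoprotein of wounded tissue, from 85.1 ± 11.2 to 6.05 ± 3.65 CPM.

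The rise of Cyp1a1 passed at an edgeR adjusted p = 7.02e-08 (SE 0.31 on the log2 scale). On that scale the other changes were 4.88 ± 0.31 (SE) for Cyp1b1 (adjusted p = 2.42e-07), 1.80 ± 0.11 for Nqo1 (adjusted p = 2.1e-07) and 2.52 ± 0.33 for Hmox1 (adjusted p = 1.21e-04). For Ccl2 and Tnc they were -4.18 ± 0.68 (adjusted p = 7.13e-04) and -3.81 ± 0.41 (adjusted p = 2.47e-05). All 5 CSE libraries lay beyond all 5 controls for each of these genes. In the deposited annotation, whose genome build is not given in the sources used here, Cyp1a1 (ENSRNOG00000019500) spans chromosome 8 from 62472095 to 62478147 and Cyp1b1 (ENSRNOG00000040287) chromosome 6 from 2307808 to 2316717. Hmox1 (ENSRNOG00000014117) and Nqo1 (ENSRNOG00000012772) lie on chromosome 19, from 14508616 to 14515456 and from 38422164 to 38437180. Ccl2 (ENSRNOG00000007159) spans chromosome 10 from 69412017 to 69413870 and Tnc (ENSRNOG00000058645) chromosome 5 from 79789671 to 79874671.

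**Figure D1:**
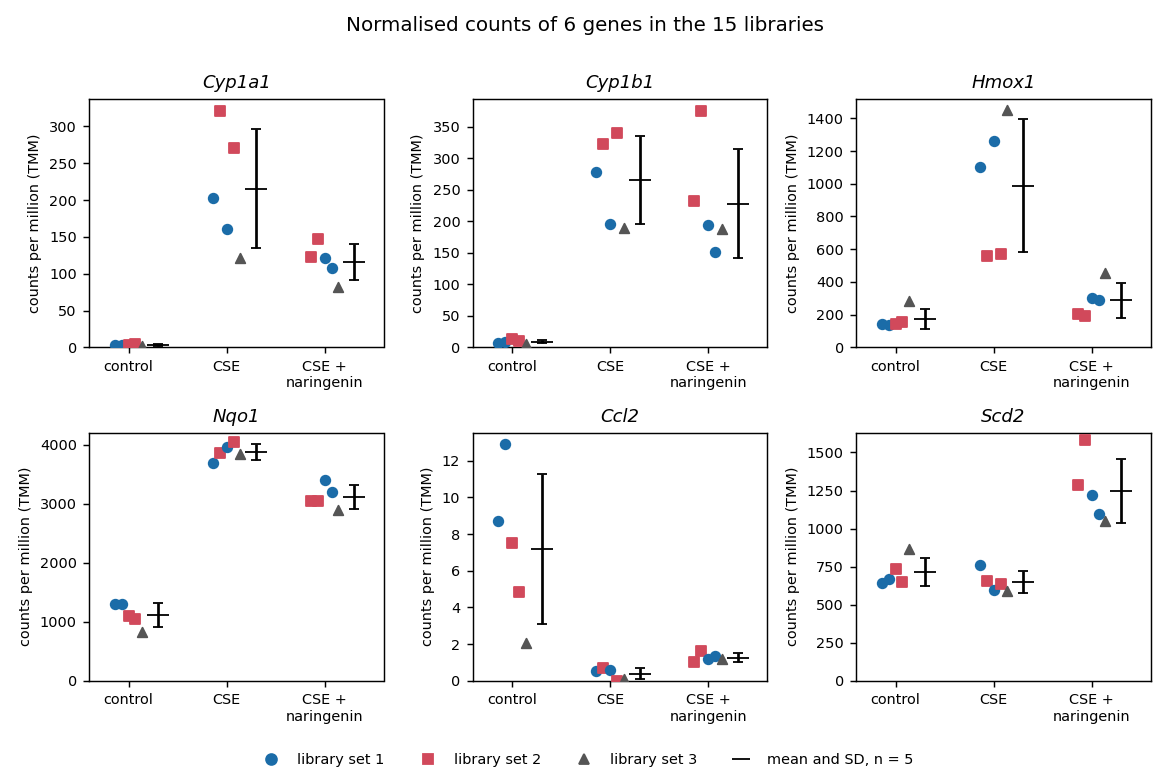
Level of 6 genes in each of the 15 libraries, in CPM scaled by TMM, by group; points are libraries, their shape and colour the library set, and bars the mean with SD of 5 libraries. Cyp1a1 averages 3.36, 215 and 116 CPM in control, CSE and CSE with naringenin, and Hmox1 172, 989 and 289 CPM.

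All 7 tested AhR targets rose with CSE, also adjusted over the list alone (median log2 3.10; camera adjusted p = 8.37e-30, and adjusted p = 1.71e-05 with an estimated correlation). Besides both cytochromes they include the AhR repressor Ahrr (log2 3.42) and the aldehyde dehydrogenase Aldh3a1, which went from 183 ± 87.4 to 1572 ± 229 CPM (log2 3.10). Of 21 antioxidant genes controlled by NRF2, 19 rose and 2 did not pass, with the same 19 adjusted over the list alone (median log2 0.87; camera adjusted p = 1.28e-43, and adjusted p = 0.00266 with an estimated correlation). Examples are Gclm, a subunit of the enzyme that limits glutathione synthesis (2.46-fold), and Tkt of the pentose phosphate pathway (log2 0.87). Gpx2 and Txn1, named after their values were seen, did not pass (log2 -0.24 and 0.32) but did with the library set as a block. Among 19 other xenobiotic and aldehyde enzymes, 7 rose, 2 fell and 10 did not pass, or 9 and 2 adjusted over the list alone (median log2 0.43; camera adjusted p = 3.54e-04, but adjusted p = 0.267 with an estimated correlation). The aldo-keto reductases Akr7a3 and Akr1b8 (log2 1.82 and 1.94) and the alcohol dehydrogenase Adh7 (log2 3.94) rose, while the sulfotransferase Sult1a1 fell by 2.08 on the log2 scale. Fatty acid genes had 7 members up, 1 down and 12 not past of 20 (7 and 2 adjusted over the list alone). Their median was log2 0.18 (camera adjusted p = 0.0182, but adjusted p = 0.161 with an estimated correlation). Among them Cpt1a, which admits fatty acids to mitochondrial oxidation, and the malic enzyme Me1 rose (log2 0.90 and 0.75). Lexm, with no role given here, was among the largest rises (log2 4.47).

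Inflammatory mediators fell with CSE in 14 of 25 tested members, and 11 did not pass (18 lower adjusted over the list alone). The list median was log2 -0.81 (camera adjusted p = 5.73e-08, but adjusted p = 0.286 with an estimated correlation). Ccl2, the growth factor Csf2 (log2 -3.54, or -2.64 without control library 5), the NF-kB subunit Relb (log2 -0.87) and its feedback inhibitor Tnfaip3 (log2 -1.47) were among them. Control library 5 stood apart here, with a list score of 1.31 against 0.321 to 0.522 in the other controls, and without it 12 members fell (median log2 -0.59). The inducible nitric oxide synthase Nos2 fell (log2 -3.87) from a control mean that rests on the same library, at 162 CPM against 17.1 to 20.5 in the others. Of 20 matrix genes 6 fell and 14 did not pass (9 lower adjusted over the list alone, median log2 -0.83; camera adjusted p = 1.11e-05, but adjusted p = 0.212 with an estimated correlation), among them Tnc and the metalloproteinases Mmp9 and Mmp12 (log2 -4.43 and -2.80). Without control library 5, 4 matrix members fell and 1 rose. Junction genes fell in 7 of 16 members, with 9 not past (1 higher and 7 lower adjusted over the list alone). Median log2 was -0.32 (camera adjusted p = 9.2e-04, and adjusted p = 0.0236 with an estimated correlation). The claudins Cldn1, Cldn4 and Cldn8, which seal or tune the paracellular path, fell by 1.37, 0.57 and 0.95 on the log2 scale. Without control library 5 the junction list had an adjusted p = 0.0534 with an estimated correlation. Basal cell genes fell in 3 of 15 members and 12 did not pass (3 adjusted over the list alone). Median log2 was -0.62 (camera adjusted p = 0.00939, but adjusted p = 0.307 with an estimated correlation). These were the keratins Krt14 and Krt17 (log2 -1.32 and -1.05) and the glycoprotein Pdpn (log2 -1.49), while Krt5 gave -0.86 ± 0.76 (adjusted p = 0.452).

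Some markers of other cell types changed too. Of 9 stromal genes 3 fell and 6 did not pass (3 adjusted over the list alone, median log2 -1.24; camera adjusted p = 0.0668): the actin-binding Cnn1 and Tagln of smooth muscle (log2 -4.70 and -2.42) and collagen Col1a1 (log2 -2.24). Their median was -0.24, -0.78 and -3.24 in library sets 1, 2 and 3. Of 7 neuroendocrine, tuft and cartilage genes Comp rose and Col2a1 and Dclk1 fell, with 4 not past (1 and 2 adjusted over the list alone, median log2 -0.97; camera adjusted p = 0.401). Of 4 endothelial genes 1 rose, Eng (log2 1.65, chosen after its value was seen), as adjusted over the list alone (median log2 0.17; camera adjusted p = 0.371). No leukocyte gene of 6 passed with edgeR and group alone, also adjusted over the list alone (median log2 -0.37; camera adjusted p = 0.517). Among them 1 lay below an unadjusted p of 0.05, DESeq2 and limma-voom called 1 and 0, and edgeR with the set as a block called 1 lower.

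Cilium genes fell in 13 of 27 members, 1 rose and 13 did not pass (16 lower and 1 higher adjusted over the list alone). The group median was log2 -0.44 (camera adjusted p = 8.94e-07, but adjusted p = 0.466 with an estimated correlation). The axonemal dynein chains Dnai1 and Dnai2 (log2 -0.57 and -0.50) and the tektin Tekt2 (log2 -0.69) fell, and Ccno, needed for centriole amplification, rose (log2 0.48, chosen after its value was seen). Mucin and goblet cell genes had 4 lower, 1 higher and 9 not past of 14 (6 and 1 adjusted over the list alone). The members had a median of log2 -0.62 (camera adjusted p = 0.0178, but adjusted p = 0.589 with an estimated correlation and 0.136 without control library 5). The anion exchanger Slc26a4 and the transcription factor Foxa2 fell (log2 -2.31 and -0.52), and Fcgbp, chosen after its value was seen, rose (log2 0.56). Muc5ac had 18, 9 and 58 reads in the 3 groups and was not tested. Club cell genes had 2 higher, 1 lower and 9 not past of 12 (2 and 2 adjusted over the list alone, median log2 -0.50; camera adjusted p = 0.46). The immunoglobulin receptor Pigr fell (log2 -0.58) from 10627 ± 868 CPM, and Scgb1a1, the main club cell secretory protein, gave -0.67 ± 0.24 (adjusted p = 0.0548; 0.0119 with the set block). Ion transport genes had 5 lower, 2 higher and 8 not past of 15 (8 and 3 adjusted over the list alone). Their median was log2 -0.57 (camera adjusted p = 0.0379, but adjusted p = 0.307 with an estimated correlation and 0.148 without control library 5). The sodium channel subunit Scnn1a, the water channel Aqp4 and the proton pump Atp12a fell (log2 -0.57, -0.72 and -1.29), and Cftr gave -1.36 ± 0.54 (adjusted p = 0.086; 3.06e-05 with the set block). Set block values for Scgb1a1 and Cftr rest in part on pairs of libraries that may repeat 1 culture.

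Other lists did not pass as groups with CSE when group was the only term. Proliferation genes had 6 lower (Plk1 -1.67 and Bub1 -1.93 on the log2 scale among them), 1 higher and 15 not past of 22 (9 and 3 adjusted over the list alone, median log2 -0.62; camera adjusted p = 0.0597). Interferon-induced genes had 3 lower and 17 not past of 20 (3 adjusted over the list alone, median log2 -0.39; camera adjusted p = 0.288), with Gbp2 and Ifit2 at log2 -2.20 and -0.71 among them and set medians of 0.21, 0.01 and -0.77. Without control library 5 the interferon median was 0.41. In the unfolded protein and integrated stress response Chac1 and Trib3 rose (log2 1.55 and 1.44), Pdia4 fell (log2 -0.25) and 17 of 20 did not pass (the same counts adjusted over the list alone). The median was -0.01, the mean 0.22 and the test pointed up (camera adjusted p = 0.427). Heat shock genes had 1 riser of 13, Hspd1 (log2 0.42, chosen after its value was seen), as adjusted over the list alone (median log2 0.25; camera adjusted p = 0.113). Of 17 p53 targets Gdf15 and Phlda3 rose (log2 1.49 and 0.32, chosen after their values were seen), 1 adjusted over the list alone (median log2 0.06; camera adjusted p = 0.634). In squamous genes Tgm1 rose and Dsg3 fell (log2 1.09 and -0.61, chosen after their values were seen) of 9, also adjusted over the list alone. Median and mean were -0.16 and -0.06, and the test pointed up (camera adjusted p = 0.952). Of 20 cholesterol genes 1 rose and 1 fell, the latter Mvd (log2 -0.51, chosen after its value was seen), also adjusted over the list alone (median log2 -0.02; camera adjusted p = 0.66). No hypoxia gene of 16 passed with edgeR and group alone, also adjusted over the list alone (median log2 -0.41; camera adjusted p = 0.0569). Of these 4 lay below an unadjusted p of 0.05, DESeq2 and limma-voom called 2 and 1, and edgeR with the set as a block called 11 lower. Control library 5 had a hypoxia score of 1.46 against -0.037 to 0.189 in the other controls, and without it the median was -0.05. Of 13 mitochondrial genes 0 passed with group alone in edgeR, DESeq2 or limma-voom, at an unadjusted p under 0.05 or adjusted over the list alone (median log2 -0.10; camera adjusted p = 0.413). With the set as a block in edgeR 2 were lower, and camera called the list lower without control library 5 (adjusted p = 0.0417). With the set block camera also called hypoxia, stromal and heat shock genes (adjusted p = 7.29e-04, 0.0113 and 0.0279, but adjusted p = 0.434, 0.219 and 0.599 with an estimated correlation), and no longer mucin genes (0.0661). With an estimated correlation the block gave an adjusted p = 0.0612 for junction and 0.0454 for fatty acid genes.

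Across all genes, 1711 were higher and 1652 lower in CSE than in control libraries at an edgeR adjusted p under 0.05, 21.2% of those tested, but 192 and 531 at 2-fold or more. With the library set as a block, chosen after seeing the data, 6325 passed (3051 higher, 3274 lower), including all 3363, and 4001 (1812 and 2189) on counts summed per set and group. Contrasts within sets 1 and 2 gave 4473 and 4111 genes, tested on the spread within pairs of libraries that may repeat 1 culture. Of the 3363, 3309 had the same sign in all 3 sets. For 2157 of the 3363 the groups did not overlap, which fixes that sign. In 749 of the 15860 genes tested the CSE effect differed between sets (edgeR interaction of group and set, adjusted p under 0.05). Set 3 enters that test with 1 library per group. On the authors' FPKM values, limma put 2338 genes higher and 1078 lower. The median log2 fold change of all genes was 0.0623 on FPKM against -0.00255 with TMM scaling. In 14.6% of genes the groups did not overlap, against 0.794% by chance. Best1 was no longer called without control library 4 (adjusted p = 0.0544), Ccnb1 without control library 2 or CSE library 5 (up to 0.0568), and Cdc20 without control library 2 or 5 or CSE library 2 or 5 (up to 0.0691). Muc1 lost the call without control library 2 or 5 or CSE library 1, 2, 3 or 4 (adjusted p up to 0.102). Tagln and Dclk1 lost it without control library 3 or 4 or CSE library 1, 3 or 5 (up to 0.0634 and 0.0902), and Col1a1 without any of these or control library 5 (up to 0.11).

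The second comparison, the question the treatment groups pose, asks what naringenin changes in exposed cells. Hmox1 was at 289 ± 107 CPM (SD, n = 5) with naringenin against 989 ± 406 CPM in CSE alone, a fall to 0.292 of its level. Lexm fell from 21 ± 7.66 to 4.51 ± 1.35 CPM, and the aldo-keto reductases Akr1b8 and Akr7a3 to 0.513 and 0.537 of their level in CSE alone. Scd2, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, rose 1.92-fold from 649 ± 70.3 to 1246 ± 210 CPM, and the semaphorin Sema7a 2.54-fold from 11.1 ± 3.67 to 28.1 ± 2.86 CPM. Ciita, the master activator of MHC class II genes, rose 2.23-fold from 2.37 ± 0.311 to 5.28 ± 1.11 CPM. The cytochromes did not pass, with Cyp1a1 at 116 ± 24.1 CPM (log2 -0.89 ± 0.25, adjusted p = 0.1) and Cyp1b1 at 228 ± 87 CPM (log2 -0.22 ± 0.26, adjusted p = 0.796). Nqo1 gave -0.32 ± 0.11 (adjusted p = 0.182). With the library set as a block Cyp1a1 and Nqo1 passed (adjusted p = 3.31e-04 and 0.0134) and Cyp1b1 did not (0.332), and on counts summed per set and group only Cyp1a1 did.

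On the log2 scale the change was -1.78 ± 0.32 (SE) for Hmox1 (edgeR adjusted p = 0.0181), -2.22 ± 0.34 for Lexm (adjusted p = 0.00606), 0.94 ± 0.12 for Scd2 (adjusted p = 0.00183), 1.34 ± 0.17 for Sema7a (adjusted p = 0.00183) and 1.16 ± 0.14 for Ciita (adjusted p = 0.00161). The 5 libraries of either group did not overlap for any of these, which the rule for named genes required of the largest rises and falls. Scd2 (ENSRNOG00000046005) spans chromosome 1 from 264059374 to 264072433, Sema7a (ENSRNOG00000007687) chromosome 8 from 62723788 to 62745868, and Ciita (ENSRNOG00000002659) chromosome 10 from 5213350 to 5260608. Further large rises were Art4 (log2 1.44), Ccna1 (1.24), Mmd (1.21) and Sema6a (1.11), and further large falls Krt20 (log2 -1.44), the peptide transporter Slc15a1 (-1.31), Zfand2a (-1.23) and Cpt1a (-0.97).

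Of 21 NRF2-controlled genes 4 fell and 17 did not pass (13 lower adjusted over the list alone, 15 with the set as a block). The group median was log2 -0.34 (camera adjusted p = 1.22e-16, and adjusted p = 0.0474 with an estimated correlation, which became 0.0938 without control library 5 and 0.00874 with the set block). Besides Hmox1 they were the autophagy receptor Sqstm1 (log2 -0.72), the biliverdin reductase Blvrb (-0.36) and Me1 (-0.36). No AhR target of 7 passed with edgeR and group alone (2 lower adjusted over the list alone and at an unadjusted p under 0.05; DESeq2, limma-voom and edgeR with the set block called 2, 0 and 2), with a median of -0.22 (camera adjusted p = 0.00292, but adjusted p = 0.0918 with an estimated correlation). Other xenobiotic enzymes had 2 lower, Akr7a3 and Akr1b8, and 17 not past of 19 (3 lower and 1 higher adjusted over the list alone, 6 and 2 with the set block). The median was log2 -0.11 (camera adjusted p = 0.00915, but adjusted p = 0.407 with an estimated correlation). Cholesterol synthesis genes had 2 higher, Mvd and Dhcr7 (log2 0.61 and 0.55), and 18 not past of 20 (3 adjusted over the list alone, 4 with the set block). Their median was log2 0.20 (camera adjusted p = 4.09e-06, but adjusted p = 0.258 with an estimated correlation). Among fatty acid genes Scd2 rose, Cpt1a, Me1 and Hadha fell and 16 of 20 did not pass (2 and 6 adjusted over the list alone, 4 and 7 with the set block). The median was 0.04, the mean -0.06 and the test pointed down (camera adjusted p = 0.435).

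Like the AhR targets, 5 other lists passed camera at the preset correlation alone, with no member past the threshold in edgeR with group as the only term. With the set as a block 11 cilium genes were higher and 0 lower, 5 and 1 mucin genes, 8 and 1 matrix genes, 0 and 9 heat shock genes, and 0 and 6 hypoxia genes. List members were not counted on counts summed per set and group, where far fewer genes passed in this comparison. Cilium genes had a median of 0.23 (camera adjusted p = 5.39e-06, but adjusted p = 0.485 with an estimated correlation), with 5 of 27 higher at an unadjusted p under 0.05, none adjusted over the list alone, and 0 with DESeq2 or limma-voom. Pifo gave 0.30 ± 0.10. Mucin and goblet cell genes had a median of 0.42 (camera adjusted p = 0.00297, but adjusted p = 0.466 with an estimated correlation), with 3 of 14 higher adjusted over the list alone, at an unadjusted p under 0.05 and with DESeq2, and 0 with limma-voom. Foxa2 gave 0.41 ± 0.10 (adjusted p = 0.0674). Matrix genes had a median of 0.52 (camera adjusted p = 0.00549, but adjusted p = 0.407 with an estimated correlation), with 4 of 20 higher and 1 lower adjusted over the list alone, 5 and 1 at an unadjusted p under 0.05, 3 and 1 with DESeq2 and 0 with limma-voom. Tnc gave 1.65 ± 0.38 (adjusted p = 0.0563). Heat shock genes had a median of -0.41 (camera adjusted p = 8.94e-07, but adjusted p = 0.312 with an estimated correlation), with 6 of 13 lower at an unadjusted p under 0.05, none adjusted over the list alone, and 0 with DESeq2 or limma-voom. The small heat shock protein Hspb1 gave -1.34 ± 0.44 (adjusted p = 0.178), with CSE library 5 at 723 CPM against 150 to 293 in the other CSE libraries. Hypoxia genes had a median of -0.26 (camera adjusted p = 0.0422, but adjusted p = 0.732 with an estimated correlation), with 2 of 16 lower at an unadjusted p under 0.05, none adjusted over the list alone, and 0 with DESeq2 or limma-voom. CSE library 5 was the highest of its group in Ldha, a glycolytic enzyme of that list, at 1807 CPM against 974 to 1078.

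The remaining lists did not pass with naringenin when group was the only term. Pdia4 rose (log2 0.32, chosen after its value was seen) among 20 stress response genes, 2 adjusted over the list alone (median log2 0.06; camera adjusted p = 0.0686). In the others no member passed with edgeR and group alone, and counts in the next sentences are of members adjusted over the list alone. Medians and camera adjusted p were 0.11 and 0.268 for 25 inflammatory genes (none), 0.12 and 0.189 for 20 interferon-induced genes (1 higher), 0.11 and 0.81 for 22 proliferation genes (none), 0.15 and 0.379 for 12 club cell genes (none), -0.36 and 0.0569 for 9 squamous genes (none), and 0.15 and 0.0668 for 15 ion transport genes (none). They were 0.39 and 0.415 for 9 stromal genes (none), -0.63 and 0.189 for 6 leukocyte genes (none), 0.23 and 0.377 for 7 rare cell genes (1 higher), and -0.03 and 0.555 for 13 mitochondrial genes (none). In 4 lists the median, mean and test differed in sign: p53 targets (17 members, none; 0.06, -0.03, down; camera adjusted p = 0.693), basal cell genes (15, none; -0.06, 0.00, up; 0.941), junction genes (16, 1 lower; 0.01, 0.01, down; 0.684) and endothelial genes (4, 1 lower; 0.16, -0.13, down; 0.54). At an unadjusted p under 0.05 these 14 lists had from 0 to 3 members higher and from 0 to 2 lower. Limma-voom called 1 member, an endothelial gene, and DESeq2 called 1 each in the interferon, ion transport, junction, endothelial and rare cell lists. EdgeR with the set as a block called 7 stress response genes higher, 4 interferon genes higher and 1 lower, 4 ion transport and 3 inflammatory genes higher, 3 p53 targets lower, and 1 basal gene each way. It called 1 rare cell gene higher, 1 squamous, 1 junction and 1 endothelial gene lower, and 0 in the other 5. With that block camera called the stress response, squamous and ion transport lists (adjusted p = 0.0453, 0.0355 and 0.0109, but adjusted p = 0.54, 0.366 and 0.255 with an estimated correlation).

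**Figure D2:**
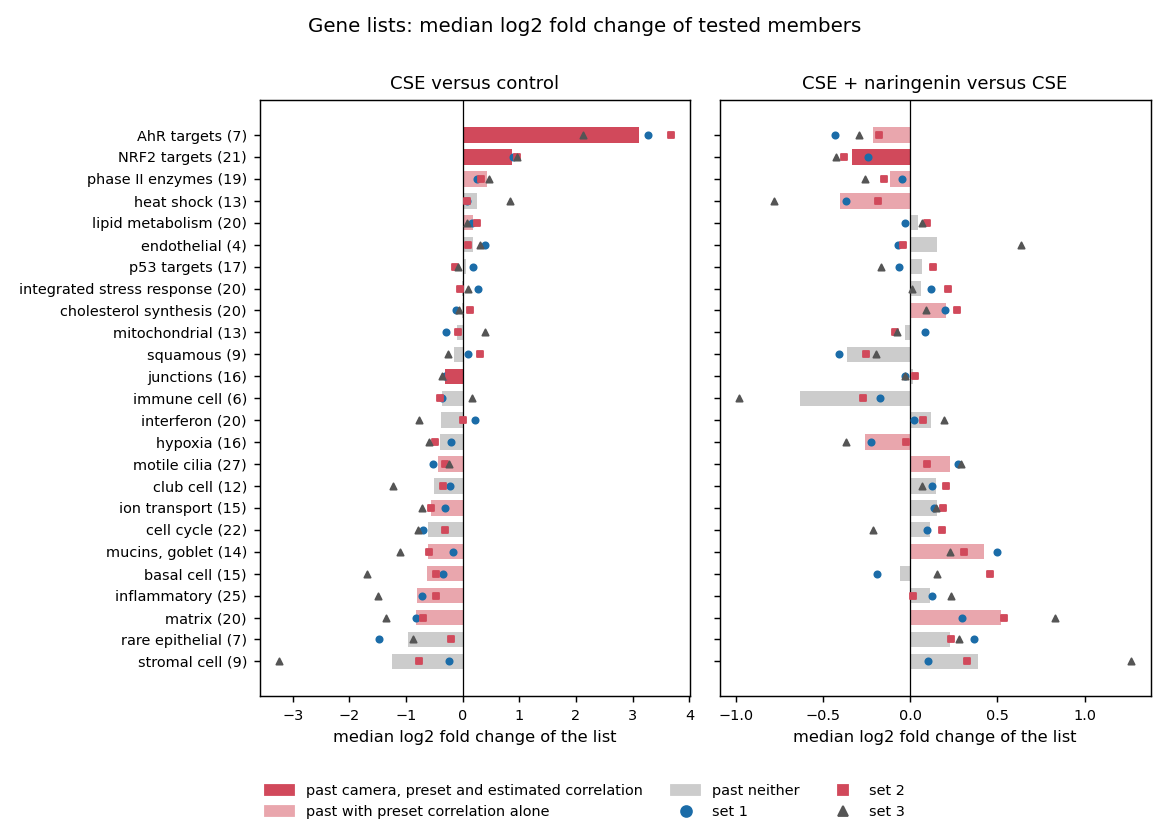
Median log2 fold change of the tested members of each of the 25 gene lists, for CSE versus control and for CSE with naringenin versus CSE; bars are medians over genes, dark red where camera passed with the preset and the estimated correlation, pale red with the preset alone and grey with neither, and points are the medians within library sets 1, 2 and 3. AhR targets reach 3.10 with CSE and -0.22 with naringenin, and NRF2-controlled genes 0.87 and -0.34.

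Naringenin with CSE gave 53 genes higher and 91 lower than CSE alone (edgeR adjusted p under 0.05), 0.908% of those tested, and 2091 at an unadjusted p under 0.05. At 2-fold or more there were 10 higher and 6 lower. With the library set as a block 2015 passed (1057 higher, 958 lower), including all 144, but 180 (102 and 78) on counts summed per set and group, so which direction has more calls depends on the fit. On these sums Ccna1, Mmd, Sema6a, Krt20, Blvrb, Me1, Dhcr7 and Hadha were not called. Contrasts within sets 1 and 2 gave 666 and 639 genes, again on the spread within such pairs of 1 set and group. All 144 had the same sign in all 3 sets, but for 142 of them the groups did not overlap, which fixes that sign. The count fell to 86, 86, 48, 65 or 86 without CSE library 1, 2, 3, 4 or 5, and to 36, 93, 72, 66 or 67 without CSE with naringenin library 1, 2, 3, 4 or 5. Hmox1 was no longer called without CSE library 3 or CSE with naringenin library 1 (adjusted p up to 0.0647), Art4 without CSE library 3 (0.0534), Mvd without CSE library 1, 3 or 5 or CSE with naringenin library 1 (0.0744), and Cpt1a without CSE library 4 or CSE with naringenin library 1, 3, 4 or 5 (0.0712). Ccna1, Mmd, Sema6a, Krt20, Zfand2a, Sqstm1, Blvrb, Me1, Dhcr7 and Hadha each lost the call without any of 6 to 10 libraries (adjusted p up to 0.0953 for Ccna1 and 0.133 for Hadha).

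Both comparisons use the CSE libraries, and naringenin calls lay mostly opposite to those of CSE. Of the 144 genes, 75 had risen with CSE and fell with naringenin, and 44 had fallen with CSE and rose with naringenin, against 9.82 and 5.52 for independent lists of these sizes. The annexin Anxa7 rose by 0.45 with CSE and fell by 0.58 with naringenin on the log2 scale. Ciita (log2 -2.50 then 1.16), Ptpru (-1.56 then 0.97), Gna14 (-0.87 then 0.97), Sema7a (-1.91 then 1.34) and Nt5e (-0.87 then 0.58), the ecto-nucleotidase that makes adenosine, fell with CSE and rose with naringenin. A single gene, LOC681458 (ENSRNOG00000013279), rose in both (log2 1.13 and 1.29), and 24 naringenin calls, Scd2 and Dhcr7 among them, were not called in CSE versus control. LOC681458 has a placeholder name and was chosen after its values were seen. Simulated unchanged groups sharing the CSE libraries gave no calls in either comparison in 20 draws, so they set no expected number of opposite or same-direction genes. Across genes, which are not independent replicates, the fold changes correlated at r = -0.638 (covariance -0.148), against a simulated mean of -0.491 (covariance -0.0464). With the CSE libraries split 2 against 3 between the comparisons, 20 splits averaged 24.2 opposite genes (0 to 84) and 0.2 same-direction genes, r = -0.349 and a covariance of -0.12. In those splits a mean of 1800 genes were called for CSE and 35.3 for naringenin, on fewer CSE libraries, so 24.2 does not compare with 119. The count of 119 opposite genes became 73, 78, 41, 58 or 73 without CSE library 1, 2, 3, 4 or 5, 33, 76, 66, 59 or 59 without CSE with naringenin library 1, 2, 3, 4 or 5, and 74 or 289 without control library 4 or 5. The count of 1 in the same direction became 3 without control library 5, 4 without CSE with naringenin library 2, and 0 without CSE library 3, 4 or 5 or CSE with naringenin library 1, 3 or 5. With the library set as a block 1480 genes changed in opposite directions and 59 in the same direction, but 154 and 3 on counts summed per set and group.

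**Figure D3:**
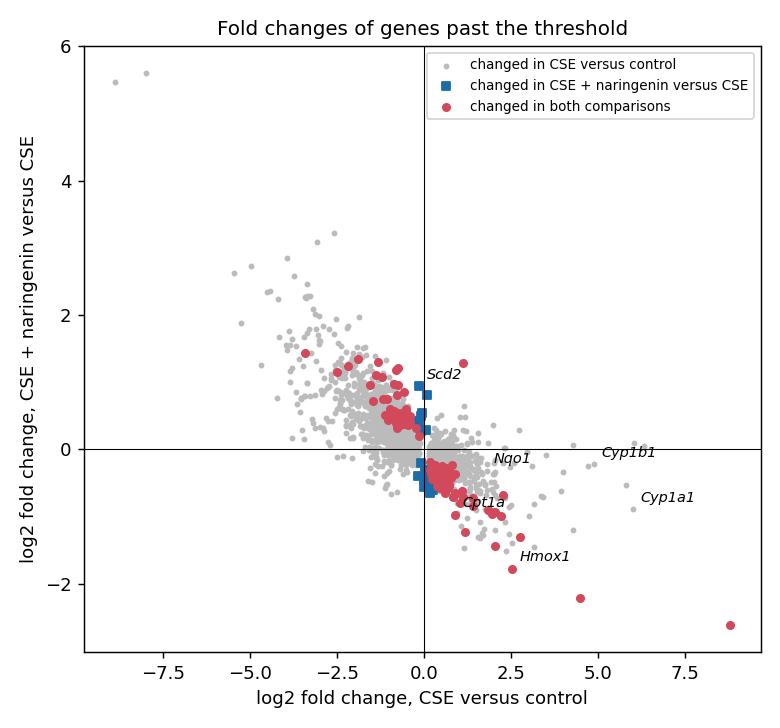
Log2 fold change of CSE versus control (horizontal) against that of CSE with naringenin versus CSE (vertical), each point a gene past the threshold in at least 1 of the comparisons, coloured by whether it passed in both. Of the 144 genes called with naringenin, 119 passed in both with opposite signs and 1 with the same sign.

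The third comparison asks which transcripts still differ from control cells when CSE is given with naringenin. Cyp1a1 stood at 116 ± 24.1 CPM (SD, n = 5) against 3.36 ± 0.967 CPM in control, 34.5-fold higher, and Cyp1b1 25.3-fold higher at 228 ± 87 CPM. Nqo1 was 2.79-fold higher at 3116 ± 197 CPM and Aldh3a1 7.24-fold higher at 1326 ± 365 CPM. Hmox1, at 289 ± 107 CPM against 172 ± 61.9 CPM, did not pass (log2 0.75 ± 0.31, adjusted p = 0.156; adjusted p = 0.00232 with the set block). Ca3, a carbonic anhydrase, fell from 24.5 ± 5.12 to 2.23 ± 1.36 CPM, and Tnc from 85.1 ± 11.2 to 18.9 ± 8.13 CPM.

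On the log2 scale these were 5.11 ± 0.30 (SE) for Cyp1a1 (edgeR adjusted p = 4.13e-07), 4.66 ± 0.30 for Cyp1b1 (adjusted p = 1e-06), 1.48 ± 0.11 for Nqo1 (adjusted p = 2.87e-06), 2.86 ± 0.27 for Aldh3a1 (adjusted p = 2.19e-05), -3.46 ± 0.43 for Ca3 (adjusted p = 2.55e-04) and -2.17 ± 0.38 for Tnc (adjusted p = 0.00316). Other large rises were Adh7 (log2 3.32), the activin subunit Inhbe (2.90) and Ahrr (2.72), and other large falls Crct1 (log2 -3.63), Cnn1 (-3.45), Depp1 (-3.22), Rgs16 (-2.83) and Csf2 (-2.78). Depp1, Csf2 and Rgs16 rest in part on control library 5, at 184, 11.5 and 6.31 CPM against 11.1 to 30.9, 1.75 to 2.84 and 1.09 to 2.65 in the other controls. Without it they gave log2 -1.76, -1.88 and -2.17, and Csf2 and Rgs16 did not pass.

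AhR targets rose in 6 of 7 members, all 7 adjusted over the list alone (median log2 2.72; camera adjusted p = 9.22e-37, and adjusted p = 1.25e-05 with an estimated correlation). Their median was 2.78, 2.9 and 0.72 in library sets 1, 2 and 3. Nfe2l2, which encodes NRF2, did not pass over all genes (log2 0.19, named after its value was seen). NRF2-controlled genes rose in 14 of 21 members, 18 adjusted over the list alone (median log2 0.56; camera adjusted p = 1.72e-31, and adjusted p = 0.0072 with an estimated correlation), with Tkt and Gclm at 0.79 and 1.06. Other xenobiotic enzymes had 5 higher, 1 lower and 13 not past of 19 (6 and 1 adjusted over the list alone, median log2 0.14; camera adjusted p = 0.00837, but adjusted p = 0.407 with an estimated correlation), with Akr7a3 and Akr1b8 at 0.93 and 0.98. Fatty acid genes had 4 higher, with Scd2 and Elovl6 at 0.81 and 0.73, and 16 not past of 20 (7 higher and 1 lower adjusted over the list alone). The list median was log2 0.20 (camera adjusted p = 0.017, but adjusted p = 0.161 with an estimated correlation). Cholesterol genes had 4 higher, with Dhcr7, Cyp51 and Idi1 among them (log2 0.47, 0.42 and 0.36), and 16 not past of 20 (5 adjusted over the list alone). Median log2 was 0.18 (camera adjusted p = 0.00795, but adjusted p = 0.467 with an estimated correlation). Stress response genes had 3 higher, Sdf2l1, Chac1 and Psat1 (log2 0.55, 1.42 and 0.63), and 17 not past of 20 (6 adjusted over the list alone). The group median was log2 0.11 (camera adjusted p = 0.0128, but adjusted p = 0.704 with an estimated correlation).

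Junction genes fell in 5 of 16 members, among them Cldn1, Cldn7 and Cldn8 (log2 -1.48, -0.36 and -0.86), and 11 did not pass (7 lower adjusted over the list alone). The members had a median of log2 -0.30 (camera adjusted p = 2.66e-06, and adjusted p = 0.00272 with an estimated correlation). Inflammatory mediators had 6 lower, with Ccl20, Ccl2 and Relb at -1.53, -2.51 and -0.75, and 19 not past of 25 (15 adjusted over the list alone). The members had a median of log2 -0.64 (camera adjusted p = 5.74e-10, but adjusted p = 0.25 with an estimated correlation). Control library 5, the highest control in their list score, read 58.9 CPM for Ccl20 against 18.9 to 23.9 in the other controls. Basal cell genes had 3 lower, Krt17, Krt14 and the integrin Itgb4 (log2 -1.13, -1.18 and -0.76), and 12 not past of 15 (5 adjusted over the list alone). Their median was log2 -0.76 (camera adjusted p = 9.2e-04, but adjusted p = 0.212 with an estimated correlation). Matrix genes had 4 lower, Tnc, Mmp9, Mmp12 and the transcription factor Snai2 (log2 -1.30), and 16 not past of 20 (4 adjusted over the list alone). The median was log2 -0.60 (camera adjusted p = 2.86e-04, but adjusted p = 0.286 with an estimated correlation). Hypoxia genes had 3 lower, Pgk1, Ndrg1 and Pfkfb3 (log2 -0.76, -1.99 and -1.16), and 13 not past of 16 (4 adjusted over the list alone). Their median was log2 -0.55 (camera adjusted p = 2.65e-05, but adjusted p = 0.467 with an estimated correlation). Ndrg1 was at 1413 CPM in control library 5 against 128 to 289 in the other controls, and without that library 1 hypoxia gene was higher and 0 lower (edgeR), with a median of -0.34. Cilium genes had 1 lower, Tekt2 (log2 -0.49), and 26 not past of 27 (1 adjusted over the list alone). The list median was log2 -0.18 (camera adjusted p = 0.00555, but adjusted p = 0.708 with an estimated correlation). Proliferation genes had 1 lower, Ccnb1 (log2 -1.53), and 21 not past of 22 (none adjusted over the list alone, median log2 -0.60; camera adjusted p = 0.0193, but adjusted p = 0.704 with an estimated correlation), and the list did not pass without control library 5 (camera adjusted p = 0.0891).

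Among the remaining lists, none of which passed camera with group alone, club cell genes had Cyp2b1 and Aldh1a7 higher (log2 0.88 and 0.75), Pigr lower (log2 -0.38) and 9 not past of 12, also adjusted over the list alone (median log2 -0.32; camera adjusted p = 0.762). Named after their values were seen, Slc26a4 fell among 14 mucin genes (log2 -1.73; 1 adjusted over the list alone, median log2 -0.16; camera adjusted p = 0.415), and Gdf15 rose among 17 p53 targets (log2 1.13; 1 adjusted over the list alone; camera adjusted p = 0.704). The p53 median and mean were -0.02 and -0.00, and the test pointed up. Also named after their values were seen, Tgm1 rose and Dsg3 fell among 9 squamous genes (log2 0.86 and -0.97; 1 and 2 adjusted over the list alone, median log2 -0.28; camera adjusted p = 0.202). Clcn2 rose and Scnn1a fell among 15 ion transport genes (log2 1.01 and -0.39; 2 and 2 adjusted over the list alone, median log2 -0.29; camera adjusted p = 0.202), again named after their values were seen. The leukocyte gene Coro1a, so chosen too, fell (log2 -0.74; 2 of 6 adjusted over the list alone, median log2 -1.05; camera adjusted p = 0.0569). Cnn1 was the stromal member of 9 that fell (1 adjusted over the list alone, median log2 -0.85; camera adjusted p = 0.0696), with set medians of -0.73, -0.55 and -1.75. No member passed with edgeR and group alone, over all genes or adjusted over the list alone, among 20 interferon-induced genes (median log2 -0.12; camera adjusted p = 0.682), 13 heat shock genes (-0.24; 0.181), 4 endothelial genes (0.48; 0.436), 7 rare cell genes (-0.04; 0.697) and 13 mitochondrial genes (-0.15; 0.113). At an unadjusted p under 0.05 these had 2, 1, 0, 2 and 0 members, DESeq2 called 1 interferon gene, and limma-voom called 0 in all 5 lists. With the set as a block edgeR called 2 interferon genes higher and 5 lower, 5 heat shock genes lower, 1 rare cell gene each way, 1 mitochondrial gene lower and 0 endothelial genes. Camera with that block called the stromal list (adjusted p = 0.0112, but adjusted p = 0.219 with an estimated correlation). Without control library 5 camera called the mitochondrial genes lower (adjusted p = 6.57e-04), and the interferon median turned to 0.50 (camera adjusted p = 0.131).

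CSE with naringenin gave 675 genes higher and 619 lower than control (edgeR adjusted p under 0.05), 8.16% of those tested, but 91 and 139 at 2-fold or more. With the library set as a block 4192 passed (1995 higher, 2197 lower), including all 1294, and 1640 (631 and 1009) on counts summed per set and group, where Cyp51 and Idi1 were not called. Contrasts within sets 1 and 2 gave 2524 and 2247 genes, again on the spread within pairs of 1 set and group. Of the 1294, 1281 had the same sign in all sets. For 953 of the 1294 the groups did not overlap, which fixes that sign. On the authors' FPKM values, limma put 1179 genes higher and 445 lower, with an all-gene median log2 fold change of 0.0551 against 7.88e-05 with TMM scaling. Without CSE with naringenin library 1, 3 or 4 the count fell to 791, 755 or 859. Of 54 named calls, 19 were lost without some library. Cyp51 was lost without control library 4 (adjusted p = 0.0534), Depp1 without CSE with naringenin library 1 (0.0505), and Csf2 without control library 5 or CSE with naringenin library 4 or 5 (up to 0.0677). Ccl2 was lost without control library 2 or CSE with naringenin library 1, 3 or 5 (adjusted p up to 0.0596), Chac1 without control library 3 or 4 or CSE with naringenin library 3, 4 or 5 (up to 0.065), and Rgs16 without control library 5 or CSE with naringenin library 1, 3, 4 or 5 (up to 0.0736). Snai2 was lost without control library 2 or 5 or CSE with naringenin library 1, 4 or 5 (adjusted p up to 0.0724), and Mmp12 without control library 3 or 4 or CSE with naringenin library 1, 3 or 4 (up to 0.0755). Cnn1, Psat1, Ccnb1, Tekt2, Krt14, Mmp9, Idi1, Acaca, Pgk1, Ndrg1 and Pfkfb3 each lost the call without any of 6 to 9 libraries (adjusted p up to 0.113 for Ndrg1). Il6, with 4, 4 and 0 reads in control, CSE and CSE with naringenin, was not tested. Il1b gave -1.21 ± 0.85 with CSE and -1.94 ± 0.89 for CSE with naringenin against control, neither past the threshold (adjusted p = 0.341 and 0.202).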

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

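The tests of depth, of the mitochondrial share and of a property of the whole set of control library 5 were chosen only after the result was seen. Within each group of 5 libraries, a gene or list score was picked out where the gap between the highest or lowest library and its nearest neighbour exceeded 0.71 of the group's range (Dixon's criterion). This happened 66 times in 477 groups, or 13.8 per 100, and chance flags about 1 in 20 groups. Control library 5 accounts for 30, CSE library 5 for 13, CSE with naringenin library 5 for 8 and CSE with naringenin library 2 for 7.

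In control library 5, hypoxia and glycolysis genes stood above the other controls, in CPM: Ndrg1 1413 (others 128 to 289), Ldha 2168 (1122 to 1287), Pgk1 902 (442 to 551), Aldoa 1702 (1166 to 1231). Others were Pfkfb3 125 (29.2 to 44) and Depp1 184 (11.1 to 30.9). So did inflammatory and matrix genes: Nos2 162 (17.1 to 20.5), Csf2 11.5 (1.75 to 2.84), Tnfaip3 125 (34.5 to 43.6), Ccl20 58.9 (18.9 to 23.9). Cxcl10 was at 14.9 (1.2 to 1.62), Il1b 0.594 (0.188 to 0.296), Plaur 41.9 (14.3 to 15.2) and Mmp13 114 (15.8 to 21.1). Higher too were Aldh3a1 335 (123 to 177), Akr1b8 491 (269 to 314), Hmox1 283 (139 to 154), Nfe2l2 212 (180 to 187), Slc1a6 13.9 (1.02 to 2.6), and, among epithelial genes, Creb3l1 36.8 (23.6 to 26.2), Scgb1a1 1092 (433 to 571), Atp12a 69.9 (22 to 35.1), F11r 454 (361 to 379) and Cldn4 1115 (713 to 760). The dynein chain Dnai1, at 76.5 (118 to 132), and Mmp9, at 0.891 (2.24 to 2.73), were lower. Its list scores were 1.31 for inflammatory genes (others 0.321 to 0.522), 1.77 for interferon-induced genes (-0.391 to -0.23), 1.46 for hypoxia genes (-0.037 to 0.189) and -0.341 for mitochondrial genes (0.156 to 0.199).

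CSE library 5 was highest in Nos2 6.95 CPM (others 1.72 to 2.59), Atp12a 24 (9.94 to 14), Cldn4 645 (516 to 538), Zfand2a 195 (62.4 to 95.4), Bag3 98.5 (62.2 to 66). It was highest in Hspb1 723 (150 to 293), Aldoa 1631 (1190 to 1303), Pfkfb3 54.2 (31.8 to 33.3), Ldha 1807 (974 to 1078) and Pgk1 602 (330 to 380), and lowest in the ciliogenesis factor Myb, 3.6 (6.52 to 7.3). Its interferon score was 0.901 (-0.532 to -0.213) and its cilium score -0.546 (-0.193 to -0.139). CSE with naringenin library 5 was highest in Nos2 16.2 CPM (4.36 to 6.12), Cxcl10 7.05 (0.197 to 0.885), Mmp13 53.4 (8.17 to 14.3), Acan 1.31 (0.301 to 0.523), Aldoa 1297 (1024 to 1058) and Pgk1 449 (291 to 328) and lowest in Me1, 174 (196 to 203). It had an interferon score of 1.3 (-0.373 to -0.282). CSE with naringenin library 2 was highest in Aldh3a1 1966 (1054 to 1262), Relb 17.7 (15.8 to 16.2), Cpt1a 93.5 (64 to 71.8), Elovl6 8.52 (5.98 to 6.39), Col2a1 2.1 (0.472 to 0.833). The same held for Mvd 43.4 (30.3 to 33.7) and Ccl20 15.8 (7.8 to 9.98). Control library 3 was highest in Art4, 4.46 (2.77 to 2.86), and lowest in Nt5e, 675 (798 to 831), and control library 2 was lowest in the rare cell score, -0.441 (0.233 to 0.358). CSE library 2 was highest in Ccna1, 4.86 (3.95 to 4.07), and Sema6a, 1.45 (0.608 to 0.837), and CSE library 1 in the ion transport score, -0.038 (-0.351 to -0.298). CSE library 4 was lowest in Creb3l1, 14.5 (18.8 to 19.9), and Sdf2l1, 15.5 (19.2 to 20.1).

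Several of these lie in control library 5, and it could carry a property of library set 3, the replicates numbered 5, or act alone. In 2 of 6 pairs of list and group the set 3 library lay beyond the other 4 on the same side. Both pairs are hypoxia genes, while inflammatory genes did not. Control library 5 was within the controls for stromal genes, so the stromal pairs could not count. Set 3 was itself found from the likeness of its libraries, and the question stays open. The 6 pairs leave out interferon-induced genes, where control library 5 stood furthest above the other controls and both other set 3 libraries lay beyond their groups on the same side. It does not make the falls with CSE alone, since 1419 of the 1652 genes called lower, or 85.9%, kept the call without it and all 1652 kept their sign. No biological explanation was tested, as the labels name no animal or culture.

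The 3 library sets cut across the groups, and sequencing depth, RNA quality or the animals of origin might set them apart. Depth is unlikely: sets held 4.99% of the spread of library totals (permutation p = 0.766, 9999 permutations). With the mitochondrial share as a covariate 7585 of 8071 genes, or 94%, still differed between sets, though the share itself had 37.4% of its spread between them (permutation p = 0.091, n = 15). Since the sets were found in these same counts, some of those differences were built in, and the 94% does not settle RNA quality. For genotype, 0 genes were on (at least 5 CPM) throughout 1 set and off (at most 0.1 CPM) throughout another, and the highest count in 100 random assignments was also 0. This leaves genotype open, since animals need not differ by all-or-none genes and the labels give no strain.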

How the results depend on the processing

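The library set block, sums of libraries within sets, set 3 left out, limma on FPKM and list tests without control library 5 were chosen after seeing the data; the pseudocount alternative does not apply to counts. No call reversed: of 4569 alternative values for named genes 4559 kept their direction, and those that did not belong to Krt5 in CSE with naringenin versus CSE, which was not past the threshold. With DESeq2 Wald tests 607 genes passed for CSE with naringenin versus CSE and 2100 versus control, with 452 changed in opposite directions and 10 in the same direction. Limma-voom gave 2 in the same direction. Without a low-count filter 78 passed for CSE with naringenin versus CSE, 66 of them opposite, and with the stricter filter 220. A fit of only 2 groups gave 833 versus control. A fold of at least 2 gave 723, 16, 230 and 13 for the 3 comparisons and opposite genes. Of 211 named results 154 passed, and the set block lost 0 of these calls and gained 41, but on counts summed per set and group it lost 10 and gained 15. The set block gave 6325, 2015, 4192, 1480 and 59 (same direction last), but on counts summed per set and group 4001, 180, 1640, 154 and 3. Set 3 left out gave 253, 202 and 4 (naringenin versus CSE, opposite, same), and set 3 left out with the block 5747, 1645, 3816, 1211 and 50. CSE libraries split gave 24.2, 0.2 and r = -0.349 (35.3 naringenin calls in the mean), or 496, 13 and -0.401 (731 calls) with the block. Of 75 list tests 33 passed. There were 7 with an estimated correlation, 21 with fry, 7 with the set block and an estimated correlation, and 32 or 5 without control library 5 (preset or estimated). Leaving out 1 library gave 2585 to 3501 genes for CSE versus control, 36 to 93 for CSE with naringenin versus CSE, 755 to 1409 versus control, 33 to 289 opposite, 0 to 4 in the same direction, and r from -0.692 to -0.526. Replicate numbers do not pair the samples: 7 of 15 same-numbered pairs correlated above 0.1 (-0.419 to 0.361), and the best partner shared the number in 5 of 15. The best partner shared the set in 15 of 15, but the sets were clustered on these same correlations, so this was largely fixed in advance. With the replicate number as a block 300 genes passed for CSE with naringenin versus CSE, 242 opposite and 3 in the same direction. Where these values differ from the reported ones the cause was not tested. At a depth of 55.1 to 60.6 M counts, Il6 (4, 4 and 0 reads) and Muc5ac stay below the filter.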

Other observations

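The pathway tests and the comparison of AhR with NRF2 targets were chosen only after the result was seen. Ribosome biogenesis, absent from the 25 lists, moved as a group over 299 KEGG pathways of 10 to 200 genes. With CSE 41 of its 76 genes were higher and 1 lower (median log2 0.27; camera adjusted p = 3.43e-11, and adjusted p = 0.0409 with an estimated correlation). With naringenin 2 were lower and 0 higher (edgeR; median log2 -0.16; camera adjusted p = 1.17e-08, but adjusted p = 0.0668 with an estimated correlation). Pentose and glucuronate interconversions, which include the UDP-glucuronosyltransferases, had 8 of 16 genes higher with CSE and 5 higher for CSE with naringenin against control (adjusted p = 0.0409 and 0.048 with an estimated correlation). Of 101 cell adhesion molecules 31 were lower and 1 higher with CSE (median log2 -0.47; camera adjusted p = 7.26e-08, but adjusted p = 0.0781 with an estimated correlation).

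Scd2 and LOC681458 are neighbours on chromosome 1. LOC681458, from 263968134 to 264004008, rose with CSE and again for CSE with naringenin against CSE (log2 1.13 and 1.29), and Scd2, starting at 264059374, was higher in the latter and not called in CSE versus control (log2 0.94). Scd, from 264160129 to 264172729, gave log2 1.29 ± 0.43 in the latter and did not pass (adjusted p = 0.187). Reads shared between these related genes were not tested.

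Relabelled groups show how often chance gives as much. Of 100 splits of the libraries, 1 gave as many genes as CSE versus control (the real one, 3363; next 516), 2 as many as CSE with naringenin versus CSE (144; highest other 660) and 1 as many as CSE with naringenin versus control (1294; 893). Exchanging labels within library sets, 1 of 36 did so each time (6325, 2015 and 4192; next 22, 0 and 111). The split with 660 genes sets CSE libraries 1, 3, 5 and CSE with naringenin libraries 3, 4 apart and so follows library set 1. As many opposite genes came from 2 of 100 splits (119; highest other 466) and as many in the same direction from 3 of 100 (1; highest other 4). For the number of lists past camera with the preset correlation chance is not excluded: 32, 48 and 11 of 100 splits gave as many as the 11, 9 and 13 lists found, up to 15, 13 and 17.

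Naringenin's changes mirror those of CSE, which could come from the CSE libraries used in both comparisons, from a uniform weakening of the response, or from effects that differ by pathway. With the CSE libraries split between the comparisons and the set as a block, the covariance stayed at -0.127 (SD 0.0156, 8 splits that overlap). Each such split left CSE libraries of sets 1 and 2 in both comparisons. Spread common to libraries of 1 set could thus stay shared. Splits with group alone that kept CSE 1 with 3 and CSE 2 with 4 gave covariances from -0.116 to -0.092. Reuse of the same libraries alone does not explain these values, but no unchanged groups were simulated for split libraries. The share of the CSE log2 fold change returned averaged 18% ± 16 (SD) over 7 AhR targets and 38.2% ± 20 over 19 NRF2-controlled genes (difference -20.2; exact two-sided permutation p = 0.0249, genes not being independent), with Cyp1b1 at 4.45%, Nqo1 at 17.6%, Hmox1 at 70.5% and Osgin1 at 80.9%. The median share was 37.2% over all 3363 genes called with CSE, 40.4% over the NRF2-controlled genes and 14.9% over the AhR targets. Medians of the other lists with at least 3 called genes ran from 2.53% (club cell) to 58.5% (mucin). All these shares use the CSE libraries in both terms. With the CSE libraries split, the median over the genes called for CSE in each split averaged 27.9% (14.2% to 38.1%). With the set block it averaged 32.8% (23.8% to 40.6%). Among the AhR targets Nfe2l2 returned 52.3% and the others from 4.45% to 20.5%. The permutation test cannot decide on a single uniform weakening on the log2 scale. It shuffles genes as if they were independent, and the shares tested carry the noise of the shared CSE libraries. AhR targets rose further with CSE than NRF2-controlled genes (median log2 3.10 against 0.87). An equal weakening of the added level would then return a smaller log2 share of AhR targets. The test therefore cannot decide on a uniform weakening of levels either. Without a group given naringenin alone, its own effect and its effect on the CSE response may not be told apart.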
